A study of Mus musculus with 6 samples.

How the data were processed

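RNA of cultured mouse macrophages was sequenced in 6 libraries, 3 labelled control (control 1 to 3) and 3 labelled M (M 1 to 3). Per the labels' protocols, RNA was taken with Trizol and a TruSeq RNA kit was used on total RNA; whether that kit kept strand information is not given in the sources used here. The series is described as macrophages exposed to oxidised low-density lipoprotein (ox-LDL), the modified lipoprotein whose uptake turns macrophages into lipid-laden foam cells. The labels call only the C libraries control and do not spell out M, so M was taken as the ox-LDL group on that ground alone. The extraction protocol, given in the same words for all 6 libraries, calls the cells ox-LDL induced and does not set the control libraries apart, so the labels leave this reading of M uncertain. Neither dose, time nor the source of the macrophages is given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

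The authors deposited 2 tables of FPKM (fragments scaled by transcript length and by the number of mapped fragments), with Ensembl transcript and gene identifiers and gene symbols as the tables give them. The mRNA table holds 50687 transcripts of 21912 gene symbols and that of lncRNA (long non-coding RNA) holds 1513 transcripts of 1260 symbols, and 0 symbols were shared between them. The genome build was mm9 per the submitters' processing notes. The aligner, the quantifier, the annotation release and any filter applied before deposit are not given in the sources used here. The tables may have been normalized separately, so levels were compared within a table only. No genome of that build was used here, so no coordinates are given.

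FPKM carry no read counts, so the depth of a library is not known in reads. Low values were compared between libraries for genes with 1 transcript, at values below 0.1 FPKM, because reads counted as whole numbers leave steps there. The most frequent ratio to control 1, at a tolerance of 0.1%, put the relative depth at 0.878 in control 2, 0.985 in control 3, 1.03 in M 1, 0.932 in M 2 and 0.999 in M 3. It rested on 10 to 22 of the 283 to 322 transcripts compared per library, so it is a rough figure, and no intervals or floors were derived from it. Some abundant genes were listed at implausibly low values: Gapdh averaged 13.1 FPKM over all 6 libraries against 1772 for Pkm and 514 for Aldoa. A value of 0 was therefore read only as listed at 0.

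For mRNA, transcripts sharing a symbol were summed to 1 gene, genes with a mean of at least 1 FPKM over the 6 libraries were kept (10390 genes), and values were tested as log2(FPKM + 1). Each lncRNA transcript with a mean of at least 0.1 FPKM (1488 transcripts) was tested as log2(FPKM + 0.1). Both tables were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes or transcripts of the table. A gene or transcript was called at an adjusted p under 0.05. All log2 fold changes are M minus control on the log2(FPKM + pseudocount) scale, which understates the change of low genes. Levels are given as mean FPKM ± SD, n = 3 per group. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 19 lists with at least 4 tested members, and again with an estimated correlation. The exact permutation test of 3 libraries against 3 cannot go below p = 0.1, which is why single genes were not tested that way.

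The groups, tests, alternatives, 27 gene lists and rule for named genes were fixed before the data were examined. There were 16 lists on macrophage biology (cholesterol synthesis, LXR targets and efflux, modified LDL uptake, lipid droplets and fatty acids, NRF2 and oxidative stress, inflammatory NF-kB targets, interferon response, alternative activation, unfolded protein and integrated stress response, lysosome and autophagy, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, apoptosis, adhesion, matrix and protease genes, and immediate-early and heat shock genes), 1 list of macrophage identity genes, 7 lists of markers of other cell types, the mitochondrial genome, ribosomal proteins and known lncRNAs. The named mRNA genes were the 8 with the highest and the 8 with the lowest log2 fold change among called genes with non-overlapping groups and a mean of at least 5 FPKM (unnamed and RIKEN models and pseudogenes left out), up to 4 called members of each biology list with the smallest adjusted p (the 2 most abundant where none was called), and 14 genes named in advance. The named lncRNAs were the 6 highest and 6 lowest called transcripts with non-overlapping groups and a mean of at least 0.5 FPKM, and up to 6 called transcripts of the known lncRNA list. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen.

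The scripts were tested on simulated data with the real means and spreads and 200 changed genes or transcripts. In the mRNA simulation of 10390 genes, 80.6% of genes changed by 0.5 on the log2 scale were recovered, 94.0% at 1 and 100% at 2, with 13 false calls among 196. Limma called 43.1% of the real genes, a far larger share than was changed here, so these figures need not carry over to the real mRNA data. In the lncRNA simulation of 1488 transcripts the shares were 10.4%, 62.7% and 89.4%, with 4 false calls among 112. The camera simulation called the shifted cell cycle list and 0 other lists. It drew each gene independently, so it does not show how camera behaves where the genes of a list vary together. In the real data the estimated inter-gene correlation was 0.134 for the cell cycle list and 0.553 for the interferon list.

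The alternatives were pseudocounts of 0.1 and 5 (mRNA) or 0.01 and 1 (lncRNA), no filter, filters of 5 (mRNA) or 1 FPKM (lncRNA), median-of-ratios scaling, quantile normalization, eBayes without trend and robust, an adjusted p under 0.01, a replicate block, each library left out in turn, transcripts tested singly for mRNA, lncRNA transcripts summed per gene, and limma's fry for the lists. Symbols with near-identical copies (histones, class I MHC genes, Gstp1, Akr1b8, Ifi27l2a and Oas genes among them) and genes that overlap another transcript are uncertain where the quantification could split or share reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.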

Results

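The data were FPKM of mRNA and lncRNA transcripts in 3 control and 3 M libraries of mouse macrophages, and the question was which transcripts differ between control and M macrophages. M was taken as the group given ox-LDL, the stimulus used to make foam cells in culture, although the labels do not spell this out. Summed mRNA values lay between 375467 and 390581 FPKM per library, and 10324 to 10376 genes reached 1 FPKM. Mitochondrial transcripts made up 3.41% to 4.50% of the mRNA FPKM, and the 10 most abundant genes took 7.30% to 7.90% of it in the control libraries and 9.36% to 9.74% in the M libraries. Over the tested mRNA genes, Pearson's r was 0.990 to 0.993 between libraries of the same group and 0.961 to 0.968 between groups. For lncRNA transcripts these ranges were 0.908 to 0.922 and 0.860 to 0.895.

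Genes are ranked here by log2 fold change on the log2(FPKM + 1) scale, among called genes averaging at least 5 FPKM, and a ratio of means would order them differently. The highest in group M was Slc40a1 (ferroportin, the cellular iron exporter; ENSMUSG00000025993), which went from 2.18 ± 0.154 to 72.9 ± 3.13 FPKM (SD, n = 3; log2 fold change 4.54 ± 0.0554 SE, limma adjusted p = 5.43e-09). Clec4n (Dectin-2, a C-type lectin receptor for fungal glycans; ENSMUSG00000023349) rose from 0.617 ± 0.0392 to 35.6 ± 2.16 FPKM. Slc7a11 (the cystine transporter subunit; ENSMUSG00000027737) rose from 9.46 ± 0.273 to 108 ± 3.39 FPKM, and Plin2 (the coat protein of lipid droplets; ENSMUSG00000028494) from 82.5 ± 3.34 to 623 ± 19.1. Cd36 (a scavenger receptor for oxidised lipoprotein; ENSMUSG00000002944) rose from 21.9 ± 2.48 to 169 ± 4.61 FPKM. The lowest on that scale were Ifi27l2a (an interferon-induced gene; ENSMUSG00000079017), from 192 ± 32.1 to 24.0 ± 0.568 FPKM, and the class I-like MHC gene H2-T24 (ENSMUSG00000053835), from 37.1 ± 5.28 to 4.43 ± 0.283. The stearoyl-CoA desaturase Scd1 (ENSMUSG00000037071) fell from 11.4 ± 0.195 to 0.815 ± 0.109 FPKM.

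Gclm, the modifier subunit of glutamate-cysteine ligase, rose from 7.19 ± 0.244 to 64.6 ± 1.97 FPKM (adjusted p = 1.26e-08). The other genes with the highest fold changes were the aldo-keto reductase Akr1b8 (log2 fold change 2.93 ± 0.0505 SE, adjusted p = 2.43e-08) and the glutathione S-transferase Gstp1 (3.08 ± 0.574, 0.0113). Gstp1 was given as 2.90, 2.44 and 0 FPKM in control 1 to 3 and 21.3, 18.8 and 17.5 in M 1 to 3. With a pseudocount of 0.1 its adjusted p was 0.0770. The other genes with the lowest were Rtp4 (-2.55 ± 0.173, 7.35e-05), Ifi44l (-2.44 ± 0.124, 1.28e-05), Irf7 (-2.44 ± 0.111, 6.04e-06) and Ifi44 (-2.39 ± 0.0701, 4.71e-07), all induced by interferon. The desaturase Scd2 was also among them (-2.24 ± 0.0540, 1.50e-07).

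Of 10390 genes tested, limma called 4480 (43.1%), 2206 higher and 2274 lower in group M. The median absolute log2 fold change of the called genes was 0.33. Of them, 245 changed at least 2-fold, 138 higher and 107 lower, with no overlap between the groups in any of the 245. Over all tested genes the groups did not overlap in 55.7%, where chance gives 10%. The count of genes changed at least 2-fold was 375 with a pseudocount of 0.1 and 117 with a pseudocount of 5, and 2907 genes passed an adjusted p under 0.01.

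**Figure D1:**
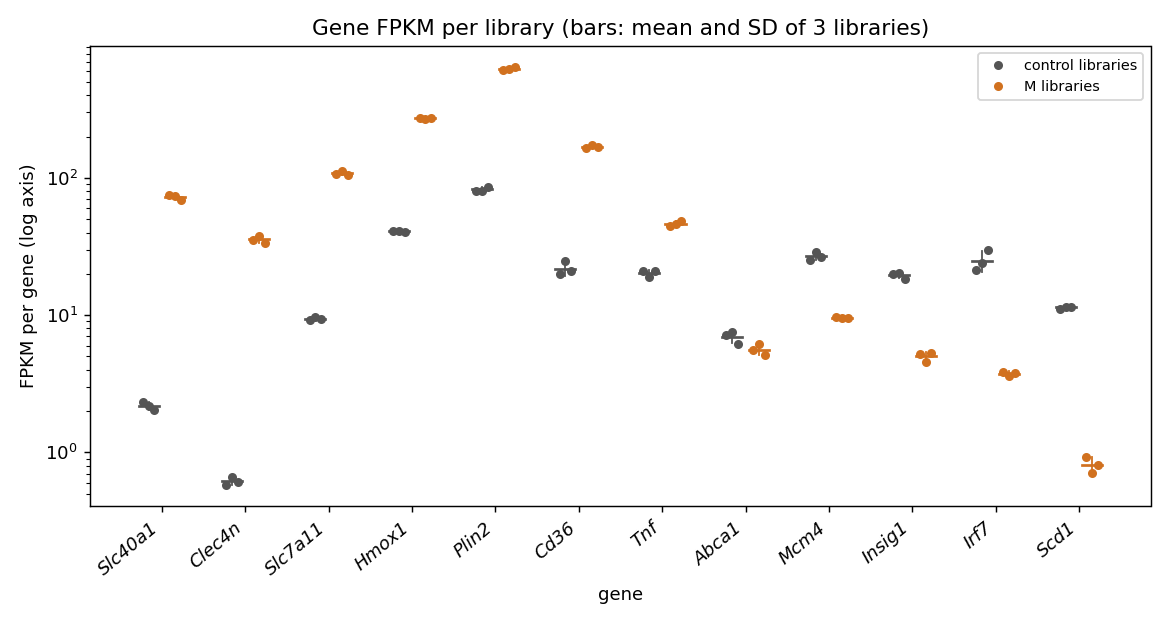
FPKM per gene (log axis) for 12 named genes in the 3 control and 3 M libraries, with 1 point per library and bars for the group mean and SD (n = 3). Slc40a1 lies at 2.18 FPKM in control and 72.9 in M on average and Scd1 at 11.4 and 0.815, while Abca1 moves least, from 6.98 to 5.59.

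Genes of glutathione and NADPH supply, haem breakdown and iron storage that the transcription factor NRF2 controls rose together. Of 23 tested list members, 22 were higher in M and 1 was lower (Keap1, the inhibitor of NRF2, log2 fold change -0.23, adjusted p = 0.0116). Hmox1 (haem oxygenase 1) went from 40.8 ± 0.532 to 271 ± 1.52 FPKM (log2 fold change 2.70 ± 0.0328 SE, adjusted p = 5.43e-09). Srxn1 (sulfiredoxin) rose by 2.61 ± 0.0409 on the log2 scale (1.49e-08), and Slc7a11 by 3.38 ± 0.0416 (5.43e-09). The list median was 1.69 (camera adjusted p = 1.32e-18; adjusted p = 0.0294 with an estimated correlation), and 22 were higher and 1 lower when adjusted over the list alone. It was the only list of the 12 called by camera, among 19 tested, that was still called with an estimated correlation. Of the 12, 7 were higher and 5 lower.

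The cholesterol synthesis genes fell. In this list 23 of 24 tested members were lower and 0 higher (the same counts adjusted over the list alone). The median was -0.77 (camera adjusted p = 9.20e-13; adjusted p = 0.0530 with an estimated correlation). Insig1, a sterol-regulated retention protein, had a log2 fold change of -1.77 ± 0.0669 SE (adjusted p = 1.89e-06), and the sterol carrier Stard4 changed by -1.57 ± 0.0580 (1.77e-06). Srebf2, the master transcription factor of the pathway, changed by -0.94 ± 0.0419 (4.07e-06).

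Of 16 tested LXR targets and efflux genes, 11 were lower and 3 higher (11 and 4 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.00373; adjusted p = 0.152 with an estimated correlation). The cholesterol exporter Abcg1 fell from 82.7 ± 0.920 to 55.5 ± 1.57 FPKM (log2 fold change -0.57 ± 0.0359 SE, adjusted p = 1.81e-05). Apoe, an apolipoprotein that accepts cellular cholesterol, fell from 3.39 ± 0.308 to 2.39 ± 0.191 FPKM (-0.37 ± 0.0827, 0.00831). The HDL receptor Scarb1, which is also in the uptake list, fell from 37.5 ± 1.93 to 20.8 ± 0.538 (-0.82 ± 0.0486, 1.28e-05). Nr1h3, which encodes LXR alpha, was higher (0.29 ± 0.0705, 0.0123), as were the apolipoprotein gene Apoc2 (0.87) and the cholesterol ester hydrolase Nceh1 (0.42). Abca1, the exporter to lipid-poor apolipoprotein, went from 6.98 ± 0.711 to 5.59 ± 0.507 FPKM (-0.28 ± 0.0873, 0.0358). The Abca1 call was lost without control 1 (adjusted p = 0.101), control 2 (0.105), M 1 (0.0819) or M 3 (0.111), with no filter (0.0626) and with quantile normalization (0.0577). With a pseudocount of 5 the list median was -0.23.

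Of 11 tested genes for uptake of modified LDL, 6 were higher and 1 lower (7 and 1 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.00798; adjusted p = 0.190 with an estimated correlation). Besides Cd36 (log2 fold change 2.90 ± 0.0734 SE, adjusted p = 2.47e-07), the scavenger receptors Stab1 (1.37 ± 0.0949, 2.66e-05) and Msr1 (0.60 ± 0.0490, 5.74e-05) and the lysosomal membrane protein Scarb2 (0.65 ± 0.0375, 1.21e-05) rose. Olr1, the LOX-1 receptor, was below the filter at 0.0181 FPKM in control and 0.0729 in M.

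Of 22 tested lipid droplet and fatty acid genes, 10 were higher and 6 lower (10 and 7 adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.0462; adjusted p = 0.295 with an estimated correlation). Plin2 rose by 2.90 ± 0.0463 SE on the log2 scale (adjusted p = 1.49e-08). Hilpda, a lipolysis inhibitor (1.67 ± 0.0733, 4.07e-06), and the triglyceride lipase Pnpla2 (0.92 ± 0.0513, 1.05e-05) rose too. Acadvl, an enzyme of fatty acid oxidation, rose by 0.66 ± 0.0356 (9.14e-06). Among the lower members were the synthetic enzymes Fasn (-1.07) and Acaca (-0.51). Pparg, a lipid-sensing nuclear receptor, was below the filter at 0.467 FPKM in control and 0.238 in M. The list call was lost without control 1 (adjusted p = 0.0504) or M 1 (0.104), with no filter (0.130), a pseudocount of 0.1 (0.0513), median-of-ratios scaling (0.0503) or quantile normalization (0.0572). Without M 3 the median was 0.16.

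**Figure D2:**
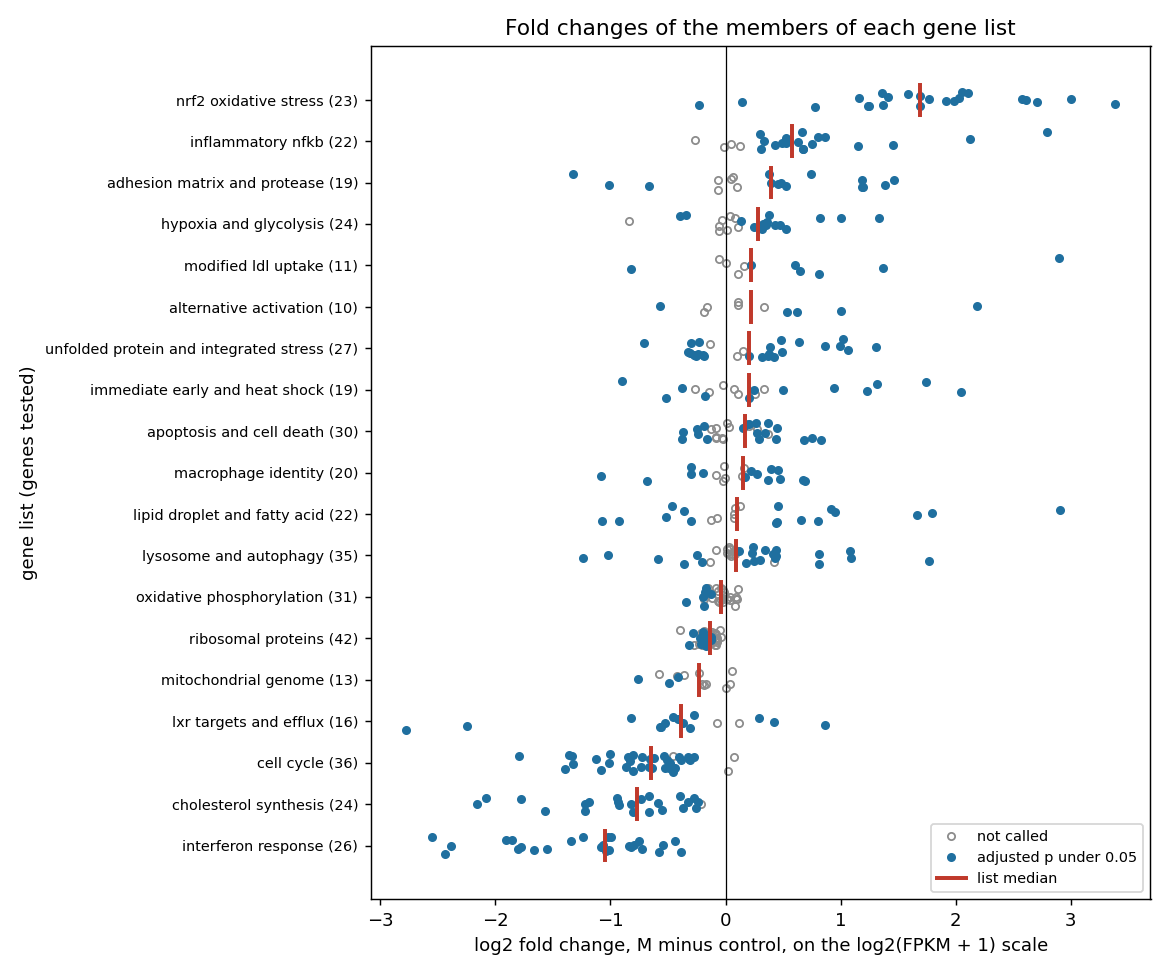
Log2 fold change (M minus control, log2(FPKM + 1) scale) of each tested member of the 19 gene lists, with filled points for genes at an adjusted p under 0.05, open points for the others, and a red line at the list median; vertical scatter within a list has no meaning. The NRF2 list has a median of 1.69, and the interferon, cholesterol synthesis and cell cycle lists have medians of -1.05, -0.77 and -0.65.

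Interferon-response genes fell without exception among the 26 tested (26 adjusted over the list alone). The median was -1.05 (camera adjusted p = 6.77e-15; adjusted p = 0.190 with an estimated correlation). Irf7, the transcription factor that amplifies type I interferon, went from 24.9 ± 4.32 to 3.75 ± 0.139 FPKM, and the antiviral synthetases Oas2 and Oas3 changed by -1.91 ± 0.0834 SE (adjusted p = 4.07e-06) and -1.78 ± 0.0809 (4.36e-06). Bst2, a member shared with the dendritic cell markers, changed by -0.84. Siglech, a marker of plasmacytoid dendritic cells from the list of other cell types, moved the same way, from 1.20 ± 0.398 to 0.172 ± 0.0257 FPKM, below the filter and untested.

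Inflammatory NF-kB targets rose in 18 of 22 tested cases and fell in 0 (19 and 1 adjusted over the list alone). Their median was 0.58 (camera adjusted p = 1.20e-07; adjusted p = 0.190 with an estimated correlation). The neutrophil chemokine Cxcl2 rose from 2.84 ± 0.473 to 25.8 ± 4.30 FPKM (log2 fold change 2.79 ± 0.140 SE, adjusted p = 1.35e-05), and the prostaglandin synthase Ptgs2 from 2.02 ± 0.370 to 12.1 ± 1.65 (2.12 ± 0.120, 1.19e-05). The cytokine Tnf rose from 20.3 ± 1.11 to 46.3 ± 2.24 (1.15 ± 0.0546, 5.09e-06), and the NF-kB inhibitor Nfkbia from 46.6 ± 2.50 to 74.9 ± 0.989 (0.68 ± 0.0456, 2.46e-05). Cxcl10, which interferon also induces, had a log2 fold change of -0.01 (adjusted p = 0.964). Of 37 members in the data, 22 passed the filter. Il1b was below it at 0.0655 FPKM in control and 0.177 in M. The untested members went both ways, among them Ccl5 (1.25 to 0.687 FPKM) and Nos2 (0.334 to 0.683). Il12b, Cxcl1, Cxcl3 and Csf2 were listed at 0 in both groups. With no filter the list median was 0.34.

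Genes of alternative activation were not called as a list (median 0.22, camera adjusted p = 0.142; adjusted p = 0.295 with an estimated correlation). Of 22 members in the data, 10 passed the filter and were tested, with 4 higher and 1 lower (5 and 1 adjusted over the list alone). Arg1, Chil3 and Retnla were listed at 0 in both groups, so the list test does not cover them. Transglutaminase Tgm2 (log2 fold change 2.18 ± 0.107 SE, adjusted p = 5.87e-06), the angiogenic factor Vegfa (1.00 ± 0.143, 0.00137) and the lectin Clec10a (0.53 ± 0.0800, 0.00125) rose, and the cytokine signalling inhibitor Socs3 fell (-0.57 ± 0.0850, 0.00124). The list median was 0.05 with no filter, 0.39 with a pseudocount of 0.1 and 0.11 with a pseudocount of 5.

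Cell cycle genes fell in 33 of 36 tested cases and rose in 0 (34 lower adjusted over the list alone). The median was -0.65 (camera adjusted p = 1.70e-15; adjusted p = 0.101 with an estimated correlation). The replicative helicase subunits Mcm4 (26.8 ± 1.68 to 9.60 ± 0.0566 FPKM, log2 fold change -1.39 ± 0.0527 SE, adjusted p = 1.92e-06), Mcm7 (-1.33 ± 0.0536, 2.54e-06) and Mcm5 (-1.02 ± 0.0409, 2.47e-06) and the ribonucleotide reductase subunit Rrm2 (-1.13 ± 0.0442, 2.17e-06) were lower. Apoptosis genes were mixed, with 12 of 30 higher and 6 lower (12 and 6 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.142; adjusted p = 0.399 with an estimated correlation). Mdm2, the p53 ubiquitin ligase (0.68 ± 0.0656, 1.27e-04), the pore-forming Bax (0.44 ± 0.0446, 1.80e-04), the inhibitor Birc3 (0.45 ± 0.0635, 9.71e-04) and the inflammasome protease Casp1 (0.37 ± 0.0394, 2.25e-04) rose. The apoptosis list median was 0.08 without M 2 and 0.10 with a pseudocount of 5.

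Genes of the unfolded protein and integrated stress responses went both ways, with 14 of 27 higher and 10 lower (15 and 11 adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.0805; adjusted p = 0.399 with an estimated correlation). Ddit3 (CHOP, log2 fold change 1.07 ± 0.0550 SE, adjusted p = 7.27e-06), the pseudokinase Trib3 (1.02 ± 0.0667, 2.15e-05), the glutathione-degrading Chac1 (1.00 ± 0.0444, 4.07e-06) and Atf3 (0.86 ± 0.0586, 2.51e-05), all induced in the integrated stress response, rose. Without control 3 this list was called (adjusted p = 0.0463). Immediate-early and heat shock genes were not called as a list (8 of 19 higher, 4 lower, the same counts adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.0930; adjusted p = 0.295 with an estimated correlation). The AP-1 subunits Fosl1 (2.05 ± 0.0944, 4.66e-06) and Fos (1.74 ± 0.0993, 1.95e-05) and the early response gene Ier3 (1.23 ± 0.105, 8.76e-05) rose, while the antiproliferative Btg2 fell (-0.90 ± 0.0710, 4.88e-05). The median of this list was 0.07 with no filter and 0.11 with a pseudocount of 5.

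Lysosome and autophagy genes were higher in 16 of 35 cases and lower in 6 (16 and 7 adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.010; adjusted p = 0.295 with an estimated correlation). Sqstm1, the autophagy receptor p62 and also in the NRF2 list, rose from 246 ± 15.5 to 837 ± 61.1 FPKM (log2 fold change 1.76 ± 0.0693 SE, adjusted p = 2.17e-06). The lysosomal acid lipase Lipa rose from 171 ± 3.79 to 364 ± 11.9 FPKM (1.09 ± 0.0427, 2.17e-06) and cathepsin L (Ctsl) from 165 ± 9.91 to 350.4 ± 9.68 (1.08 ± 0.0527, 5.72e-06). With quantile normalization the list median was 0.20.

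Hypoxia and glycolysis genes were higher in 14 of 24 cases and lower in 2 (the same counts adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.00373; adjusted p = 0.295 with an estimated correlation). The glucose transporter Slc2a1 (log2 fold change 1.33 ± 0.0668 SE, adjusted p = 6.27e-06), the hypoxia-inducible Ndrg1 (0.82 ± 0.0596, 3.30e-05), the glycolytic regulator Pfkfb3 (0.47 ± 0.0626, 6.89e-04) and pyruvate kinase Pkm (0.43 ± 0.0477, 2.64e-04) rose. The list median was 0.14 with no filter, and the log2 fold change of Pkm was 0.23 with quantile normalization (adjusted p = 0.0453). Oxidative phosphorylation genes were lower in 6 of 31 cases and higher in 0 (5 lower adjusted over the list alone). Their median was -0.04 (camera adjusted p = 0.239; adjusted p = 0.597 with an estimated correlation). Uqcrfs1 of complex III (-0.20 ± 0.0351, 0.00304), Ndufb5 of complex I (-0.17 ± 0.0332, 0.00418), Sdhb of complex II (-0.18 ± 0.0360, 0.00489) and the ATP synthase subunit Atp5a1 (-0.19 ± 0.0378, 0.00512) were lower. The log2 fold change of Atp5a1 was 9.32e-04 with quantile normalization. The oxidative phosphorylation median was -0.07 with quantile normalization, -0.02 without control 1 or control 3, -0.09 without control 2 and -0.06 without M 3.

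Adhesion, matrix and protease genes were higher in 11 of 19 cases and lower in 3 (the same counts adjusted over the list alone). The median was 0.40 (camera adjusted p = 0.00398; adjusted p = 0.152 with an estimated correlation). The urokinase receptor Plaur rose (log2 fold change 1.47 ± 0.0653 SE, adjusted p = 4.07e-06) while its ligand Plau fell (-1.33 ± 0.0650, 5.79e-06). The metalloprotease Adam8 rose (1.19 ± 0.0460, 2.06e-06) and integrin alpha 4 (Itga4) fell from 543 ± 14.8 to 268 ± 9.60 FPKM (-1.02 ± 0.0458, 4.23e-06). With no filter the list median was 0.06. Of 20 macrophage identity genes, 9 were higher and 5 lower (11 and 5 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.177; adjusted p = 0.352 with an estimated correlation). Among them lysozyme Lyz2 went from 4610 to 6069 FPKM (0.40), and the chemokine receptors Cx3cr1 (-1.08) and Ccr2 (-0.68) fell. With no filter the identity median was -0.00339.

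Ribosomal protein genes were lower in 14 of 42 cases and higher in 0 (11 lower adjusted over the list alone). Their median was -0.13 (camera adjusted p = 2.46e-04; adjusted p = 0.399 with an estimated correlation). With quantile normalization the median was 0.07 (adjusted p = 0.164). Of 13 transcripts of the mitochondrial genome, 3 were lower and 0 higher (0 called adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.105; adjusted p = 0.597 with an estimated correlation). The mitochondrial median was -0.39 without control 1 (adjusted p = 0.0553), -0.42 without control 2 (0.0191), -0.10 without control 3 (0.402) and -0.42 without M 2 (0.0458), so the list was called without control 2 or M 2.

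Markers of other cell types were mostly below 1 FPKM. Of the T and NK cell markers, 2 passed the filter, Lck (2.44 ± 0.260 to 3.72 ± 0.0935 FPKM) and Il7r (1.35 ± 0.0443 to 2.30 ± 0.263). Both were higher (2 adjusted over the list alone). Of the dendritic cell markers, 3 were tested and 2 were lower (2 adjusted over the list alone), Bst2 and Tcf4 (34.9 ± 2.11 to 29.7 ± 0.843 FPKM). Zbtb46 was not called (1.72 ± 0.119 and 1.65 ± 0.247). The neutrophil and mast cell list had 1 tested gene, Csf3r (6.99 ± 0.716 and 8.15 ± 0.677 FPKM, adjusted p = 0.0944), which was called (higher) only when adjusted over the list alone, where it is the single gene tested. The endothelial and epithelial list had 1 tested gene, Vwf (1.24 ± 0.240 and 0.968 ± 0.208, adjusted p = 0.243), which was not called. In the B cell, fibroblast and muscle, and erythroid lists 0 genes passed the filter, and their most abundant members averaged 0.0674 (Jchain), 0.507 (Acta2) and 0.170 FPKM (Epor).

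Among called lncRNAs that averaged at least 0.5 FPKM and whose groups did not overlap, the largest rise was in Gm37498 (ENSMUST00000193524.1), from 1.04 ± 0.104 to 10.3 ± 0.946 FPKM (log2 fold change 3.19 ± 0.121 SE, limma adjusted p = 1.68e-05). Mir22hg, the host transcript of a microRNA (ENSMUST00000149940.1), rose from 4.72 ± 0.454 to 13.1 ± 0.783 FPKM (1.45 ± 0.0991, adjusted p = 6.42e-04). Gm20236 (1.65 ± 0.265, 0.0118), Gm42793 (1.59 ± 0.141, 0.00121), RP23-374K9.4 (1.34 ± 0.302, 0.0343) and Gm13073 (1.32 ± 0.123, 0.00131) rose as well. The lowest by the same rule were Gm37618 (-1.58 ± 0.177, 0.00287), Ftx, from the X-inactivation centre (ENSMUST00000145803.7; -1.57 ± 0.333, 0.0294), and Gm14902 (-1.55 ± 0.317, 0.0260). The microRNA host Mir99ahg (ENSMUST00000170849.7) fell from 20.1 ± 0.943 to 7.36 ± 3.03 FPKM (-1.54 ± 0.323, 0.0334). Gm29340 (-1.41 ± 0.115, 9.84e-04) and F630028O10Rik (-1.39 ± 0.164, 0.00355) fell too. Of the transcripts tested per symbol, 1 of 4 was lower for Ftx and 1 of 2 for F630028O10Rik, with the others not called, and 4 of 4 were lower for Mir99ahg. Some of these calls were lost with 1 library left out. That of RP23-374K9.4 was lost without control 2 or any M library (adjusted p = 0.0587 to 0.110), and that of Ftx without any library except control 3 (0.0509 to 0.0940). The Gm14902 call was lost without any library except control 2 (0.0530 to 0.0800), and that of ENSMUST00000170849.7 of Mir99ahg without any control library or M 2 (0.0530 to 0.0955). Another Mir99ahg transcript, ENSMUST00000182820.7 (-0.68 ± 0.131, 0.0207), lost its call without any library except control 1 (0.0515 to 0.0706) and with eBayes without trend and robust (0.0512).

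Of 1488 lncRNA transcripts tested, 158 (10.6%) were called, 52 higher and 106 lower, and 41 changed at least 2-fold, 20 higher and 21 lower. The share of higher calls was 32.9% on the deposited scale, 48.5% with median-of-ratios scaling and 46.3% with quantile normalization, and 49.5% without control 1. The median log2 fold change of all tested transcripts was -0.08 on the deposited scale, 0.00454 with median-of-ratios scaling and -0.03 with quantile normalization. By the gene type given in the table, the lower calls fell mostly on TEC (a class of annotated transcripts still awaiting experimental evidence), with 14 higher and 42 lower of 413, and on processed transcripts, with 11 higher and 35 lower of 325. Intergenic lincRNAs had 17 higher and 15 lower of 364 and antisense transcripts 6 higher and 7 lower of 268. With 1 library left out the count of called lncRNAs was 95 without control 1, 66 without control 2, 95 without control 3, 100 without M 1, 62 without M 2 and 66 without M 3.

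The list of known lncRNAs had 55 tested transcripts of 21 symbols, of which 2 were higher and 11 lower (17 called adjusted over the list alone). Neat1, the scaffold RNA of nuclear paraspeckles, rose from 360.1 ± 17.2 to 538 ± 25.8 FPKM (ENSMUST00000174287.1; log2 fold change 0.58 ± 0.0740 SE, adjusted p = 0.00492), although with quantile normalization its log2 fold change was 0.31 (adjusted p = 0.0571). Trp53cor1 (lincRNA-p21, a p53-induced RNA) rose from 6.17 ± 0.476 to 10.1 ± 1.75 FPKM (0.69 ± 0.140, 0.0250). Of 7 Dleu2 transcripts tested, 4 fell and 3 were not called. Those that fell were ENSMUST00000182756.7 (-0.60 ± 0.0954, 0.0116), ENSMUST00000183079.7 (-1.03 ± 0.174, 0.0137), ENSMUST00000182286.1 (-0.89 ± 0.209, 0.0388) and ENSMUST00000182325.7 (-1.12 ± 0.268, 0.0401). Lower too were Epb41l4aos (ENSMUST00000146010.2, -0.54 ± 0.0960, 0.0164; 1 of 2 transcripts tested) and the small nucleolar RNA host Snhg5 (ENSMUST00000180563.8, -0.47 ± 0.0857, 0.0167). Of 3 Snhg5 transcripts tested, 2 were lower and 1 was not called. The other lower one, ENSMUST00000182872.2 (-1.16 ± 0.255, 0.0322), lost its call without any library except M 2 (0.0749 to 0.0997) and with eBayes without trend and robust (0.0556). Malat1, the most abundant lncRNA named in the list, was given at 3575 ± 465 and 3607 ± 275 FPKM (adjusted p = 0.939). The Trp53cor1 call was lost without any library except M 1 (adjusted p = 0.0509 to 0.0814), that of ENSMUST00000183079.7 without M 3 (0.0515). The call of ENSMUST00000182286.1 was lost without any library except control 3 (0.0586 to 0.0997), and that of ENSMUST00000182325.7 without any of the 6 (0.0565 to 0.108). Both were also lost with median-of-ratios scaling (0.0517 and 0.0607), quantile normalization (0.0631 and 0.0641) and eBayes without trend and robust (0.0750 and 0.0717). The Epb41l4aos call was lost without M 2 (0.0570) or M 3 (0.0594), and that of Snhg5 without control 3 (0.0519) or M 3 (0.0565). With quantile normalization the calls of Epb41l4aos (-0.38, adjusted p = 0.148) and Snhg5 (-0.26, 0.166) were lost, and with median-of-ratios scaling that of Epb41l4aos (0.0515). With eBayes run without trend and robust, the calls of RP23-374K9.4, Ftx, ENSMUST00000170849.7 of Mir99ahg, Trp53cor1, Epb41l4aos, ENSMUST00000180563.8 of Snhg5 and ENSMUST00000182756.7 of Dleu2 were lost (0.0512 to 0.0717).

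**Figure D3:**
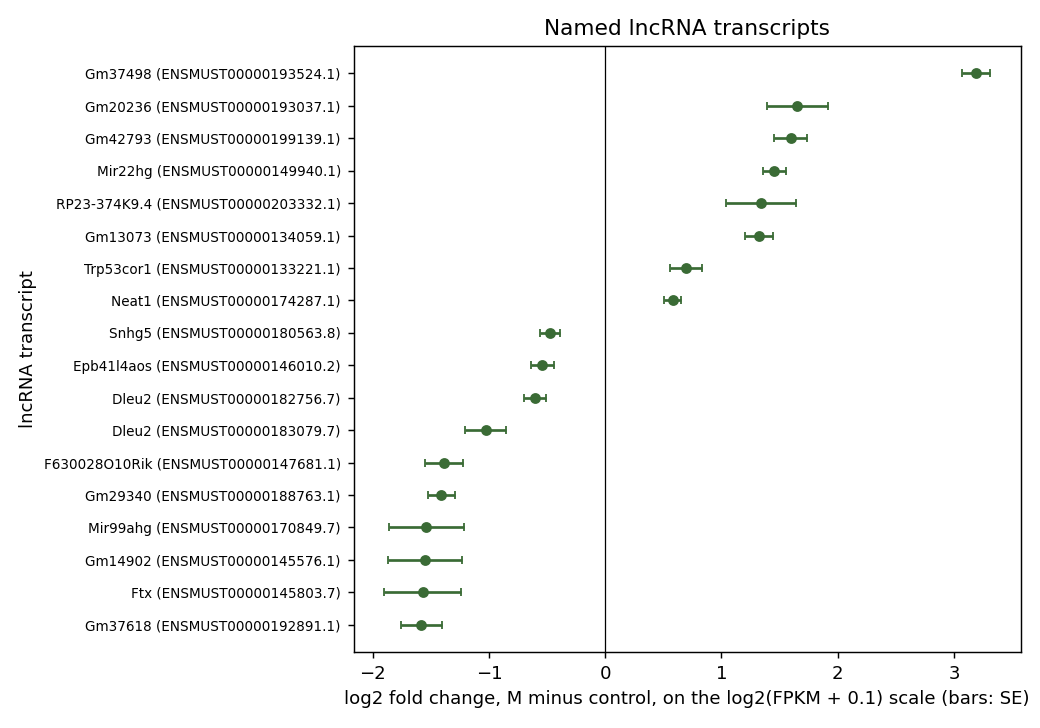
Log2 fold change (M minus control, log2(FPKM + 0.1) scale) of the 18 named lncRNA transcripts, with points for the estimate and bars for its SE from limma. Gm37498 stands at 3.19 and the lowest, Gm37618, at -1.58.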

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

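No test in this part was chosen after the results were seen. Of the 1404 values of named genes and transcripts under other settings, 1341 kept their direction and side of the threshold. With quantile normalization Atp5a1 (9.32e-04) and the ribosomal protein median (0.0693) changed sign, as did 20 of the 4480 called mRNA genes; the cause was not tested. Counts of changes of at least 2-fold followed from the pseudocount by construction: 375 mRNA genes at 0.1 and 117 at 5, and 12 lncRNAs at 1. With an adjusted p under 0.01 there were 2907 mRNA genes (1433 higher, 1474 lower) and 37 lncRNAs (17 higher, 20 lower, 15 at least 2-fold). Lower lncRNAs numbered 69 with median-of-ratios scaling and 66 with quantile normalization, and eBayes without trend and robust called 90 lncRNAs, 50 lower; the cause was not tested. Of the lists called, 1 remained with an estimated correlation. With fry, which asks whether a list's genes differ at all rather than more than other genes, 17 of 19 lists were called, the 12 of camera among them (18 without regard to direction). The 5 others were alternative activation (adjusted p = 1.00e-04), immediate-early and heat shock (0.00121), the unfolded protein and integrated stress list (0.00152), apoptosis (0.0131) and macrophage identity (0.0168). With 1 library left out, fewer samples gave 62 to 100 called lncRNAs (23 to 47 higher, 39 to 61 lower, 21 to 38 at least 2-fold) and 3686 to 4285 mRNA genes. The lncRNA simulation recovered 62.7% of changes of 1 on the log2 scale, so uncalled lncRNAs are not shown to be unchanged.

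With the replicate number as a replicate block, 4300 mRNA genes and 66 lncRNAs were called (25 higher, 41 lower, 26 at least 2-fold). Calls not made with the block were those of the lipid droplet list (adjusted p = 0.0667), RP23-374K9.4 (0.0820), Gm14902 (0.0820), Trp53cor1 (0.05001), ENSMUST00000182325.7 of Dleu2 (0.0670) and ENSMUST00000182872.2 of Snhg5 (0.0734), and the block changed no other call of a list or of a gene named by the rule. Libraries of the same number did not deviate together (r = 0.0664, 0.00520 and -0.0347 for mRNA and 0.0817, 0.00839 and -0.00368 for lncRNA), and not every library correlated best with its own number.

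Other splits of the 6 libraries into 3 and 3 are too few, at 10, for a share under 0.05; 1 of the 10, the real one, reached its own count in each case. The real split called 4480 mRNA genes (highest other 1), 158 lncRNAs (highest other 1) and 12 gene lists (highest other 9). Every other split mixes control and M libraries, so the group difference widens the spread within its groups. Few genes or transcripts can then be called, and these counts do not measure false calls. Camera at the preset correlation still called 3 to 9 lists in the other splits, so a list call at that setting does not by itself set the real groups apart.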

Other observations

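The gene families below, and the tests on interferon, LXR and isoforms, were chosen only after the results were seen. For the opposite-strand pairs, only the test of Spearman's rho was set beforehand. Replication-dependent histone genes, which supply new nucleosomes during DNA synthesis, were lower in 61 of 66 tested cases and higher in 0 (median log2 fold change -0.73, limma camera adjusted p = 5.90e-22 over 9 families; adjusted p = 0.102 with an estimated correlation). Hist1h1b, for example, went from 416 ± 23.0 to 202 ± 4.91 FPKM (SD, n = 3). Replication fork genes, 6 of them also in the cell cycle list, were lower in 32 of 39 and higher in 0 (median -0.68, adjusted p = 1.39e-13; adjusted p = 0.102 with an estimated correlation). Cytoplasmic aminoacyl-tRNA synthetases went the other way, with 14 of 17 higher and 2 lower (Qars and Vars; median 0.31, adjusted p = 1.22e-04; adjusted p = 0.120 with an estimated correlation), and Rars rose from 57.4 to 99.8 FPKM. Histone genes share near-identical sequences, so their single values are uncertain.

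Subunits of the constitutive proteasome rose in 18 of 34 tested cases and fell in 0 (median 0.14, adjusted p = 1.22e-04; adjusted p = 0.120 with an estimated correlation), though quantile normalization gave 16 higher and 1 lower. The interferon-inducible immunoproteasome subunits and regulators were lower in 4 of 5 (median -0.48, adjusted p = 0.00271; adjusted p = 0.102 with an estimated correlation): Psmb8, Psmb9, Psmb10 and Psme1. Class I MHC and peptide-loading genes were lower in 8 of 15 and higher in 0 (median -0.48, adjusted p = 1.52e-04, and adjusted p = 0.120 with an estimated correlation). H2-D1 was level at 213 and 216 FPKM (limma adjusted p = 0.739). H2-K1 varied widely between libraries, at 47.3 ± 15.6 FPKM in control and 9.66 ± 13.6 in M, and was not called (limma adjusted p = 0.0933). Iron-handling genes were higher in 10 of 19 and lower in 3 (median 0.21, adjusted p = 0.00193; adjusted p = 0.102 with an estimated correlation), but 5 of them are also in the NRF2 list, and the 14 others, with 5 higher and 3 lower, had a median of -0.02 (adjusted p = 0.321; adjusted p = 0.351 with an estimated correlation). Beside Slc40a1, the endosomal metal transporter Slc11a1 rose from 31.0 to 147 FPKM and the ferritin heavy chain Fth1 from 2092 to 4956, and the transferrin receptor Tfrc from 26.3 to 43.8. C-type lectins were higher in 7 of 13 and lower in 3 (median 0.53, adjusted p = 0.0338; adjusted p = 0.120 with an estimated correlation). Clec4n, Clec4d (26.5 to 183 FPKM) and Clec4e (21.9 to 117), receptors of 1 family, rose the most, and Clec12a fell (71.0 to 35.1). Glutathione S-transferases were higher in 5 of 10 and lower in 1 (Mgst3; median 0.44, adjusted p = 0.0178; adjusted p = 0.118 with an estimated correlation).

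When mRNA transcripts were tested singly (16851, of which 3158 were called), 27 of 3825 genes with at least 2 tested transcripts had transcripts called in both directions, 9 of them at least 2-fold each way: Lrsam1, Mbnl1, Pds5b, Pgls, Ptrh2, Rab7, Sec31a, Swi5 and Zfp827. Of these 9, 8 were called so without control 1 or M 1, 7 without M 3 and 6 without control 2, control 3 or M 2. Rab7 was lost in all of these but M 1, Mbnl1 without control 2, control 3, M 1 or M 2, Zfp827 without control 2, control 3 or M 2, and Pgls without M 3. The sets themselves varied with the library left out, at 19, 12 and 18 genes without control 1, 2 and 3 and 23, 16 and 23 without M 1, 2 and 3, and genes called in both directions at any size numbered 42 without M 1. For Lrsam1, 1 transcript went from 2.39 ± 0.177 to 0.00199 ± 0.00143 FPKM and another from 2.29 ± 0.213 to 6.25 ± 0.404. Rab7 transcript ENSMUST00000113598 was given at 21.5, 0.103 and 0.176 FPKM in M 1 to 3. The quantifier is not given, so a change in isoform use cannot be told apart from a different division of shared reads between transcripts.

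Interferon-response genes were lower in group M in all 26 tested cases (list adjusted p = 0.190 with an estimated correlation). A difference in scaling is argued against, since the list median stayed at -1.04 after quantile normalization. Fewer T, B, granulocyte, stromal or erythroid cells were examined through their markers. With markers listed at 0 left out, the other 36 had a median of 0.0548 FPKM in control. That median pools the lineages, so it does not speak for each lineage alone. Of the 4 markers at 1 FPKM or more in control, Csf3r (6.99 to 8.15 FPKM), Lck (2.44 to 3.72) and Il7r (1.35 to 2.30) averaged higher in M. Vwf (1.24 to 0.968) averaged lower. These values give no sign of fewer T cells or granulocytes, but they do not show that such cells were present. The T cell markers Cd3d, Cd3e and Cd3g and the granulocyte markers S100a9, Ly6g and Mpo were listed at 0 in both groups. Cd4 averaged 0.0459 FPKM in control and 0.00995 in M. The other lineages, with low values that may be misestimates, are not decided. Of 10 dendritic markers besides Bst2, 3 reached 1 FPKM in control, with a median log2 difference of -0.23. They were Tcf4 (34.9 to 29.7 FPKM), Zbtb46 (1.72 to 1.65) and Siglech (1.20 to 0.172), which fell unequally. The highest of the others in control was Clec9a at 0.180 FPKM, and Flt3, Cd209a and Ccr7 were listed at 0. Most dendritic markers were thus near the floor. Because such values may be misestimates, fewer dendritic cells cannot be told apart from a change in the macrophages. A treatment effect in the macrophages stays open and untested.

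Of the LXR list 11 of 16 members were lower and 3 higher, and of the cholesterol synthesis list 23 of 24 were lower (camera adjusted p = 0.152 and adjusted p = 0.0530 with an estimated correlation). Sterol loading raises LXR target transcripts while it lowers those of cholesterol synthesis. The LXR list also holds efflux genes, so not all of its members need follow LXR alone. Scaling is argued against by the LXR list median of -0.35 after quantile normalization. Of the 13 LXR list members other than Srebf1, Scd1 and Scd2, 8 were lower. With 11 of 16 lower, leaving out 3 members could not give a smaller count. It therefore does not test a fall in Srebf1 output alone, which stays open. The median of these 13 members was -0.31, but 3 were higher and the values ran from -0.82 to 0.87. They do not decide on sterol loading, which stays open. A treatment effect that lowers both sets may be considered as a hypothesis, untested here.

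Reads of a partner gene may enter the estimate of an opposite-strand lncRNA. Log2 fold changes were compared across 43 pairs of such lncRNAs (transcripts summed per gene for this test) and the genes they are named for. Spearman's rho was 0.269 (permutation p = 0.0827, adjusted over 2 tests 0.0827), which missed the threshold of p under 0.05 set beforehand. Pearson's r, not part of the test set beforehand, was 0.380 (permutation p = 0.00981, adjusted over the same 2 tests 0.0196). Both correlations are across genes, which are not independent replicates. Without the 2 pairs farthest from the median partner value, r was 0.379 and rho 0.202. The 2 log2 fold changes had the same sign in 24 of the 43 pairs, and both were called in 3, with Map2k3os and Ptgs2os2 higher and Brip1os lower like their partners, though the transcript of Ptgs2os2 tested singly was not called (adjusted p = 0.0787 against 0.0481). A shared locus and shared reads cannot be told apart here, since the use of strand in the quantification is not given in the sources used here.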
